A study of Mus musculus with 10 samples.

How the data were processed

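RNA levels were measured in 5 groups: 3 germ cell fractions, whole testis and a pool of 11 somatic tissues. Per the labels, testes were dissociated with hyaluronidase, trypsin and collagenase, cells were separated on a discontinuous Percoll gradient, and RNA was amplified and labelled as biotin cRNA. The series description states that the fractions were checked by microscopy and RT-PCR. Arrays came in 2 designs with different probe sets, and each design held 5 arrays, 1 per group. The deposited values are an intensity per probe set on a linear scale, and the submitters' processing notes name GCOS 1 as the software. The scaling target, the background correction and the detection calls are not given in the sources used here. The 2% trimmed means of the deposited values differed between arrays, from 383 to 484 on the first design and from 63.4 to 148 on the second. Whether the samples numbered 1 and 2 of a group came from separate preparations is not given in the sources used here. Raw image data were not analysed here.

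Each array was scaled to the 2% trimmed mean shared by the 5 arrays of its design. Signals below a floor were set to the floor, and a difference against it is given as a lower bound. The floor was the 90th percentile of the scaled signals of 68 chemosensory receptor probe sets on the first design (87.6). The second design held 14 such probe sets, fewer than the minimum of 20, so the median of all its scaled signals was used (47.0). On the first design 20380 probe sets named 1 gene, 691 several and 1555 none, with 64 controls besides, and 20351 were matched to an Entrez gene. On the second these were 14661, 245, 7605 and 64, and 14486 were matched. Probe sets with several or no genes were left out. Each gene was read from its probe set with the highest mean log2 signal, from the first design where any of its probe sets there was above the floor, which gave 18193 genes (11906 and 6287 from the 2 designs), 15698 of them above the floor in some group. Chromosomes were taken from the GRCm38.p6 gene table.

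A comparison is the difference of log2 scaled signal between 2 arrays of the same design, and a call is a difference of at least 4-fold. Each gene was read from 1 array per group, so genes were not tested across replicates. The 100 probe sets on both designs were, with limma on the log2 scaled signal of the 10 arrays (5 groups), with and without the replicate number as a block, and calls at a Benjamini-Hochberg adjusted p under 0.05. The error of a difference was the root mean square gap between the designs over 100 shared probe sets, divided by the square root of 2, and its 95% limit is 1.96 times that. Among genes with different probe sets on both designs, 277 of 327 called on the first design in pachytene against leptotene/zygotene had the same direction on the second (84.7%, against 54.1% for unrelated values), and 76 were also called there. Called again on the second design were 8 of 106 in pachytene against whole testis, 39 of 192 in whole testis against somatic mix and 1 of 6 in leptotene/zygotene against spermatogonia. In pachytene against leptotene/zygotene, differences correlated across these genes with r = 0.50. Over the 8 comparisons the share with the same direction was lowest in pachytene against somatic mix (73.6%) and in whole testis against somatic mix (74.0%), and r was lowest in pachytene against whole testis (0.34). In each of 4 comparisons (leptotene/zygotene against spermatogonia, pachytene against leptotene/zygotene and against whole testis, whole testis against somatic mix), the genes named in each direction were the 6 with the largest difference among genes above the floor in both groups and the 4 brightest among genes called against a group at the floor. Unnamed clones and genes whose other probe sets went the other way by more than 1 log2 were left out. Members of the gene lists and the 10 genes of the screen with the highest mean log2 signal over leptotene/zygotene and pachytene were named besides. The 16 gene lists covered spermatogonial, pachytene and spermatid markers, synaptonemal complex and meiotic cohesin, meiotic recombination, chromosome segregation, the piRNA pathway, DNA replication and cell cycle, Sertoli, Leydig, stromal, macrophage and organ markers, immediate-early and stress genes, X-linked genes and autosomal retrogenes. A list median was computed over members not at the floor in both groups, with members at the floor in 1 group taken at their bound, and placed among 10000 random lists of the same size matched on mean signal in 20 bins; a percentile under 1 or over 99 stands apart. Groups, lists, thresholds, the naming rule and the alternatives listed first below were fixed before the data were examined.

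The alternatives were quantile normalization, median scaling, the values as deposited, scaling to the shared probe sets, floors at the 40th and 60th percentile, a log2 of signal plus floor, the mean over probe sets, plain probe sets only, each array design alone, thresholds of 2-fold and 8-fold, and list means in place of medians. A receptor floor on both designs, comparisons without genes of other organs and the limma fits on the probe sets of both designs were added after seeing the data. Marker lists of intestine, liver, skeletal muscle, heart, kidney, brain, skin and blood, and later of pancreas, epididymis and adipose tissue, were written after the named genes had been seen. The procedure was tested on simulated data with known changes. Of these, 99 of 100 genes raised 8-fold and 73 of 100 lowered 8-fold were called, so decreases of dim genes are undercounted. None of 12144 unchanged genes was called. The simulated noise was that of the bright shared probe sets, far below 4-fold, so that outcome was set in advance. It gives no rate of false calls for these arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.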

Results

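Messenger RNA levels were measured on microarrays in 3 cell fractions of the juvenile mouse testis, in whole testis and in a mixture of somatic organs, all from C57BL/6 males. The study's title names a screen for genes of chromosome segregation in the first meiotic division. In the first wave of mouse spermatogenesis germ cells enter meiosis nearly together, so a density fraction taken at a given age is enriched for 1 stage. The spermatogonia were fraction 2 of a Percoll gradient from testes of 8-day-old mice. The leptotene/zygotene spermatocytes, in which meiotic recombination begins and chromosomes start to pair, were fraction 5 at day 12. The pachytene spermatocytes, in which homologous chromosomes are fully paired, were fraction 8 at day 15. Whole testis and the pool of 11 somatic tissues (liver, kidney, spleen, lung, heart, brain, skin, muscle, colon, stomach and intestine) were also taken at day 15. Each of the 5 groups had 2 samples, but the samples numbered 1 were all hybridised to one array design and those numbered 2 to its companion design, which carries other probe sets. Each group therefore had 1 array per design (n = 1), and each gene below was read from 1 array per group, so no p-value is given. Probe sets or genes present on both designs were used to check repeatability. The number of arrays limits the precision of every value below.

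The first design held 22690 probe sets and the second 22575. After scaling, between 55.3% (pachytene) and 64.1% (somatic mix) of probe sets lay above the signal floor of 87.6 on the first design, and between 42.7% (pachytene) and 56.0% (somatic mix) above the floor of 47.0 on the second. A comparison was measured again with the same probe sets only by the 100 placed on both designs. Their log2 differences between pachytene and leptotene/zygotene correlated across probe sets with r = 0.97, and between leptotene/zygotene and spermatogonia with r = 0.77; probe sets are not independent replicates. Genes read by different probe sets on the designs repeated less well: over 2012 genes, differences between pachytene and leptotene/zygotene correlated with r = 0.50, and 76 of 327 genes called on the first design were also called on the second. The error of a log2 difference estimated from the shared probe sets ranged from 0.18 (leptotene/zygotene against spermatogonia) to 0.31 (pachytene against somatic mix). These are bright probe sets, and whether the error includes differences between preparations or animals is not given in the sources used here. Differences of at least 4-fold were called, and a member of a gene list is said to have risen or fallen only where it passed that threshold. A difference beyond the 95% error limit of its comparison is described as higher or lower. Gene list medians were placed among 10000 random gene lists matched on signal, and that percentile describes these arrays only.

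**Figure D1:**
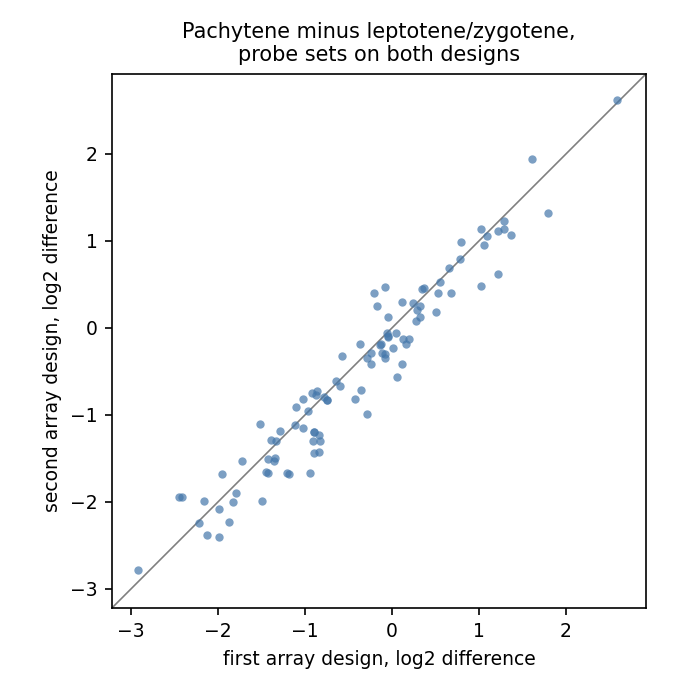
Log2 difference of scaled signal, pachytene minus leptotene/zygotene, for the 100 probe sets present on both array designs (x axis, first design; y axis, second design; the line marks equal values, each point is 1 probe set). The points lie along the line with r = 0.97, and the median gap between designs was 0.08.

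Leptotene/zygotene cells were compared with spermatogonia to find what changed at entry into meiosis. The fractions were close to each other: 40 genes were at least 4-fold higher and 36 at least 4-fold lower in leptotene/zygotene, of 12916 genes measured. The named genes that rose were expressed in the testis and near or below the floor in the somatic mix. Ldhc, the testis form of lactate dehydrogenase, went from below the floor to a signal of 1855, at least 21.2-fold higher, and Fabp9, a testis fatty acid binding protein, was at least 11.5-fold higher. Spata4 (at least 6.52-fold) and Pdcl2 (at least 5.07-fold) were higher as well. Among named genes above the floor in both fractions the largest differences were those of Tsx (log2 3.17), Zfp541 (2.82), Ropn1l (2.72), Rsph1 (2.62), Meig1 (2.59) and Morn5 (2.58). Ropn1l and Rsph1 encode parts of the sperm flagellum. Under quantile normalization the split of calls was 31 higher and 43 lower. With the values as deposited the median over genes above the floor in both fractions shifted by 0.11.

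Genes of the meiotic program were higher together, mostly by about 2-fold rather than by 4-fold. As given below, spermatogonial markers were higher too, stromal and Leydig markers were lower, and macrophage and blood markers were higher. The share of germ cells in each fraction was not measured here, so these rises are not separated from a change in that share. All 15 measured members of the synaptonemal complex and meiotic cohesin list were higher beyond the error limit of 0.35, with a median of 1.21 (percentile 100) and none past 4-fold. Sycp1, the transverse filament of the synaptonemal complex, was higher by 1.85, Terb1, which tethers telomeres to the nuclear envelope, by 1.71, and the meiotic cohesin gene Smc1b by 1.44. Of 21 measured recombination genes, 18 were higher beyond the limit and 3 lay within it (median 0.85, percentile 100). Meiob, which binds single-stranded DNA at recombination sites, rose by 2.27, and the recombinase gene Dmc1 was higher by 1.65 and Psmc3ip, its cofactor, by 1.59. Of 18 piRNA pathway and germ granule genes 15 were higher (median 0.89, percentile 100), led by Piwil1, which rose by at least 4.87-fold. The chromosome segregation list had a median of 0.59 (28 of 36 higher, 2 lower, percentile 100), with the meiotic kinetochore gene Meikin at 1.43. DNA replication and cell cycle genes were higher as well (24 of 28, median 0.64, percentile 100), among them Cdc6 at 1.39.

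Spermatogonial markers did not fall as a group between these fractions. The median of the 23 measured members was 0.51 (percentile 99.99), with 13 higher, 4 lower and none past 4-fold in either direction. The higher ones included Dmrtb1 (1.60), Id4 (1.14), Taf4b (1.11), Uchl1 (0.95), Kit (0.85), Lin28a (0.60) and Stra8, the retinoic acid target that opens meiosis (0.66). Ccnd2 (-0.97), Itga6 (-0.79) and Etv5 (-0.59) were lower, and Bcl6b, below the floor in leptotene/zygotene, was at least 1.33-fold lower.

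Transcripts of other testis cells were abundant in both fractions and shifted between them, beside the germ cell genes above. Clu, a major Sertoli cell product, had a signal of 14730 in spermatogonia and 12740 in leptotene/zygotene against 14080 in whole testis, and Cyp17a1, a steroid synthesis enzyme of Leydig cells, had 3413 and 1838 against 1025. The Sertoli list as a whole was above whole testis, with a median of 1.06 in spermatogonia and 0.83 in leptotene/zygotene. Of 18 peritubular, stromal and vascular markers 16 were lower in leptotene/zygotene (median -0.91, percentile 0), and smooth muscle Tagln fell by 2.25. All but 1 of the 8 measured Leydig markers were lower beyond the limit (median -0.80, percentile 0.09). Sertoli markers had a median of -0.22 (percentile 1.2) with 8 lower and 2 higher, and Rhox5, an X-linked homeobox gene, rose by 2.22. Macrophage and blood markers went the other way (median 1.05, percentile 100), with Lyz2 higher by 1.52. Immediate-early and stress genes were lower in leptotene/zygotene (15 of 24, 1 higher, median -0.52, percentile 0), and autosomal retrogenes of X-linked genes were higher (5 of 9, median 0.71, percentile 99.97). The named genes that fell also included epithelial and stromal ones. Cdh11, a mesenchymal cadherin, fell by 2.85, Ecrg4 by 2.86, Tbata by 2.78 and Enpep by 2.57. The phosphodiesterase gene Pde5a was 8.01-fold lower and Defb42, a beta-defensin of the epididymis, 8.02-fold lower. Against the floor, the keratins Krt8 (at least 6.44-fold) and Krt18 (at least 5.31-fold), Dner (at least 5.43-fold) and Adamts4 (at least 5.04-fold) were lower.

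The step from leptotene/zygotene to pachytene was far larger. The calls comprised 1175 genes at least 4-fold higher and 1262 at least 4-fold lower in pachytene, of 13513 measured. Some genes below the floor in leptotene/zygotene had high signals in pachytene. Hspb9, a testis heat shock protein, rose from below the floor to 11173 (at least 238-fold), Prps1l1 to 8246 (at least 175-fold), Pgam2 to 12219 (at least 139-fold) and Dkkl1, an acrosomal protein, to 7928 (at least 90.5-fold). Among named genes above the floor in both fractions the largest rises were those of Eid3 (log2 7.01), Cmtm2b (6.92), Pabpc6 (6.76), Plaat5 (6.75), Pom121l2 (6.52) and Catsperz, a subunit of the sperm calcium channel (6.52). The split of calls depended on the scaling. It was 1190 higher and 811 lower with quantile normalization, 1500 and 741 with median scaling, and 1534 and 604 when arrays were scaled to the shared probe sets. With the values as deposited it moved the other way, to 1178 higher and 1578 lower. The median over genes above the floor in both fractions was -0.25 in the main scaling and 0.12 with the shared probe sets. That median shifted by 0.17, 0.30 and 0.36 with quantile normalization, median scaling and the shared probe sets, and by 0.001 as deposited.

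Pachytene spermatocyte markers rose nearly as a block: 22 of 25 measured members were at least 4-fold higher, 24 were beyond the error limit of 0.41, and the median was 4.28 (percentile 100). Spink2, an acrosomal protease inhibitor, rose by 6.08, Crisp2 by 5.69, Tcp11 by 5.35, and the RNA-binding gene Ybx2 by 4.61. The chaperone gene Clgn rose by 4.50 and Ldhc by a further 3.66, to 23494. Pgk2, the autosomal glycolytic enzyme of meiotic cells, rose by at least 29.1-fold. Slc25a31 was the only member within the limit (-0.13). Of 24 markers of the later spermatids, 13 were below the floor in both fractions, including the transition protein genes Tnp1 and Tnp2 and the protamine gene Prm2. Of the 11 measured, 6 were higher beyond the limit and none lower (median 0.52, percentile 98.2), and Tssk1 (at least 6.31-fold) and Tekt5 (at least 5.74-fold) rose.

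Within the meiotic machinery, genes went both ways. The recombination list had a median of -0.89 (percentile 3.36), with 2 members that rose and 6 that fell among 21. Spo11, which makes the programmed DNA breaks, rose by 2.60 and Psmc3ip by 2.35, while Tex15 fell by 3.55, Dmc1 by at least 7.62-fold, Tex11 by at least 7.32-fold, Rec114 by 2.51, Brca1 by 2.34 and Mei1 by 2.04. Over all 13513 genes measured, 4053 were higher and 5948 lower beyond the error limit, so members going both ways do not set these lists apart. Of 15 synaptonemal complex and cohesin genes, 7 were higher and 6 lower. Syce1 rose by 2.15 and Stag3, a meiotic cohesin subunit, was higher by 1.44, while Syce2 was lower by 1.57 and Rec8, the meiotic kleisin, was lower, reaching the floor. The median of this list was -0.18 (percentile 65.03) and was above 0 with median scaling (0.19), as deposited (0.06) and with the shared probe sets (0.25). In the chromosome segregation list, 20 of 37 measured members were higher and 11 lower beyond the limit (median 0.48, percentile 99.75), with 3 past 4-fold in each direction. Ccna1, the meiotic cyclin A, rose by at least 23.5-fold, the Aurora kinase genes Aurkc by 3.82 and Aurka by 3.23. Ccnb2 (1.97), Meikin (1.87) and Pttg1, encoding securin (1.53), were higher without reaching the threshold. Cenpa, the centromeric histone gene, fell by 2.65, Fbxo5 by at least 5.63-fold and Ccna2 by 2.12. The somatic cohesin genes Smc1a (-1.71), Rad21 (-1.70) and Smc3 (-1.59) and the cohesin protector Sgo1 (-1.88) were lower. The piRNA list had 12 of 20 members higher and 3 lower (median 0.84, percentile 99.81). Ddx25 rose by 3.46, Piwil1 by 3.05, Tdrd7 by 2.95 and Pld6 by 2.66, while Dazl, an RNA-binding regulator of early germ cells, fell by 2.16.

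Genes of earlier germ cells and of proliferation were lower. Of 21 measured spermatogonial markers, 12 fell and 1 rose at 4-fold (median -2.16, percentile 0). Rhox13 fell by 3.84, Stra8 by 3.13, Sall4 by 2.85 and Kit by 2.67, while Dmrtb1, which acts at the switch from mitosis to meiosis, rose by 2.74 and Id4 was higher by 1.32. Of 28 replication and cell cycle genes, 10 fell and none rose (median -1.51, percentile 0.06), among them Cdt1 (-2.61), Mcm5 (-2.59) and Mcm3 (-2.42). Named genes that fell against the floor were Elavl2 (at least 17.9-fold), Lsr (at least 16.0-fold), Nop56 (at least 15.0-fold) and Ddr1 (at least 11.6-fold). Among named genes above the floor in both fractions the largest falls were those of the Leydig cell gene Cyp17a1 (-4.19), Dgkz (-3.89), Taf7l (-3.85), Rhox13 (-3.84) and Qpct (-3.79).

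X-linked genes of many functions were lower nearly as a block. Of 39 measured members of the X-linked list, 37 were lower beyond the error limit and 26 fell at least 4-fold, with a median of -2.32 (percentile 0). Taf7l fell by 3.85, Taf1 by 3.61, Pqbp1 by 3.24, the deubiquitinase gene Usp9x by at least 8.17-fold and the glycolytic gene Pgk1 by 2.53. Kdm5c (0.11) lay within the limit, and Rbmx, below the floor in pachytene, was at least 1.23-fold lower. Between leptotene/zygotene and spermatogonia the same list had a median of -0.07 (percentile 10.13; 0.08 with the values as deposited). Over all 436 X-linked genes measured, assigned through the GRCm38.p6 gene table, the median was -1.62 and 40.4% fell 4-fold, against -0.19 and 8.35% for 12977 autosomal genes; the medians of the 19 autosomes ran from -0.28 to -0.09. The list of autosomal retrogenes of X-linked genes had a median of 1.17 (percentile 99.81), with 6 of 14 that rose. It shares Pgk2, Pdha2 and Slc25a31 with the pachytene marker list, so the medians of the lists are not independent. Gk2 rose by at least 52.8-fold, Fam50b by at least 52.2-fold, Cetn1 by 4.78 and Pdha2 by 3.62. Cstf2t (0.79) and Utp14b (1.22) were higher, Timm17a (0.14) was within the limit, and the 1 member that fell, Taf9b (-2.90), is itself on the X chromosome.

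**Figure D2:**
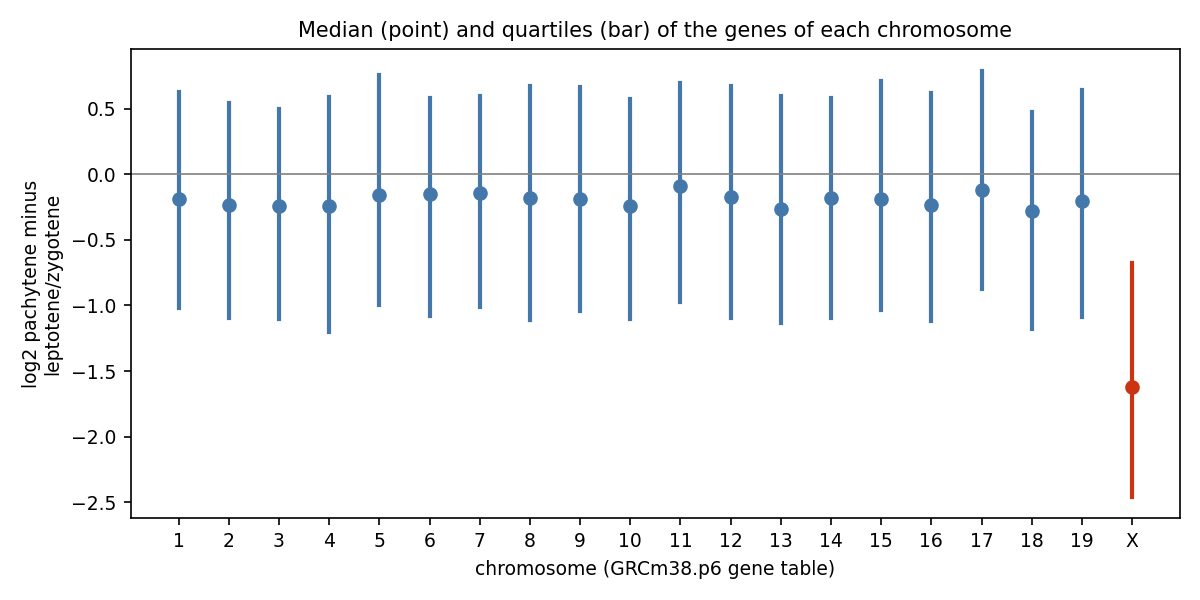
Log2 difference of scaled signal, pachytene minus leptotene/zygotene, by chromosome (x axis); points are medians over the measured genes of a chromosome and bars span the lower to the upper quartile. The X chromosome median was -1.62, below the autosome medians, which ran from -0.28 to -0.09.

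Markers of somatic testis cells were lower in the same comparison and move together with every decrease described above. Of 19 measured Sertoli markers 11 fell and none rose (median -2.42, percentile 0), among them Inhbb by 3.78, Wt1 by 3.14 and Inha by 2.42. All 8 Leydig markers were lower (median -2.03, percentile 0.26) and Cyp17a1 fell by 4.19. Stromal and vascular markers had a median of -0.95 (percentile 5.58). Macrophage and blood markers had a median of 0.76 (percentile 97.81), with Csf1r higher by 1.26. Immediate-early and stress genes were lower (20 of 23, median -1.75, percentile 0), Klf6 falling by 3.10. The 3' probe set of the 18S ribosomal RNA control also differed, from 1801 in leptotene/zygotene to 427 in pachytene on the first design and from 1814 to 342 on the second. In pachytene, Clu still had a signal of 3831 and Aard 2897.

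**Figure D3:**
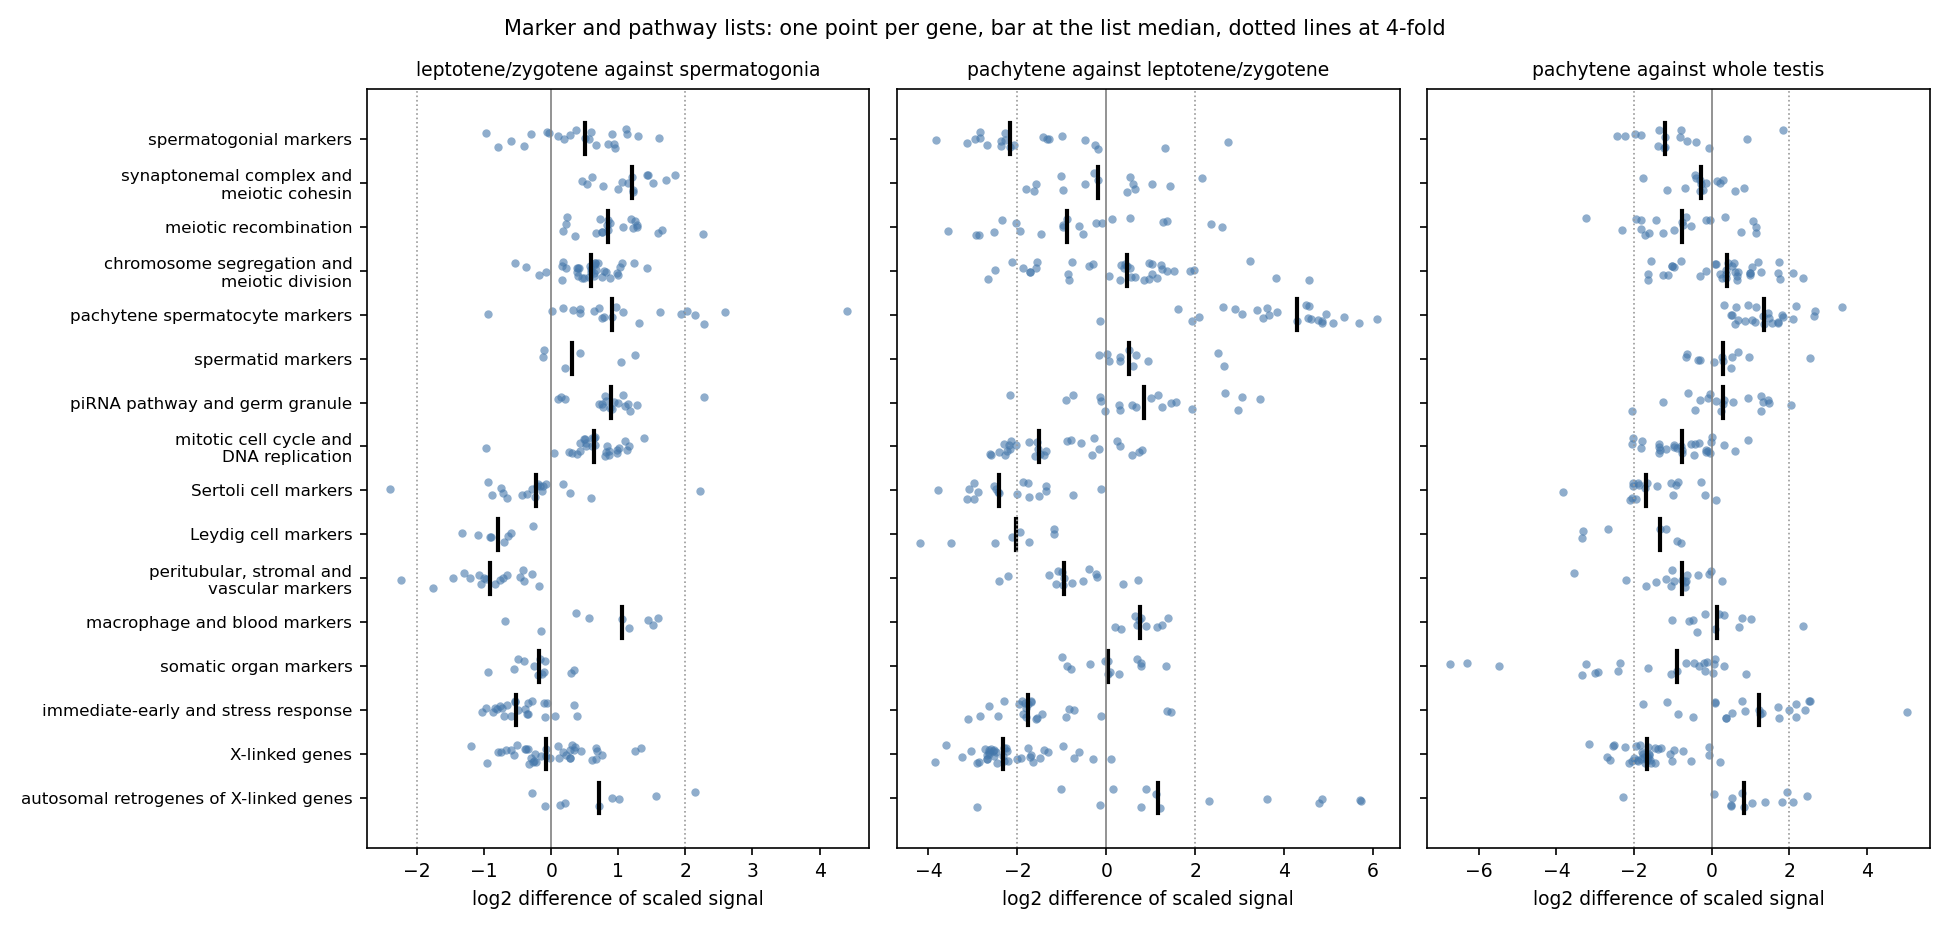
Log2 difference of scaled signal (x axis) for the members of 16 gene lists (y axis) in 3 comparisons; each point is a gene not at the floor in both groups, black bars are list medians and dotted lines mark 4-fold. In pachytene against leptotene/zygotene, the pachytene marker median was 4.28 and the X-linked median -2.32.

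Pachytene against spermatogonia, the ends of the series, gave 1374 genes higher and 1651 lower of 13694 measured (1738 and 1087 with median scaling, 1769 and 993 with the shared probe sets). The median over genes above the floor in both fractions shifted by 0.28 and 0.35 under those scalings and by 0.17 with quantile normalization. The pachytene marker list had a median of 4.86 with 24 of 25 members that rose. The synaptonemal complex list was 1.04 (percentile 99.27) with 5 of 15 that rose and none that fell, and the segregation list 0.92 (percentile 99.97) with 7 that rose and 3 that fell of 36. The recombination list, higher in leptotene/zygotene, ended at 0.31 (percentile 95.38). Spermatogonial markers were at -1.43 (percentile 0.11) and X-linked genes at -2.23 (percentile 0). Sertoli markers were at -2.43 and immediate-early genes at -2.18, both at percentile 0, Leydig markers at -2.55 (percentile 0.07) and macrophage and blood markers at 1.67 (percentile 99.79). The 3' probe set of the 18S control read 2174 and 2716 in spermatogonia on the 2 designs against 427 and 342 in pachytene.

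The pachytene fraction was set against whole testis of the same age to see what the purification enriched. There were 325 genes at least 4-fold higher and 606 at least 4-fold lower in the fraction, of 13832 measured. Pachytene markers were higher for 24 of 25 members (median 1.33, percentile 100), Ybx2 rising by 3.36 and Acr, encoding acrosin, by 2.67. The segregation list went both ways, with 17 of 36 members higher, 9 lower and 10 within the error limit of 0.46 (median 0.39, percentile 99.67). Over all 13832 genes measured, 3560 were higher and 5279 lower beyond that limit. Plk1 rose by 2.35 and Aurka by 2.09, while Smc1a (-1.64), Rad21 (-1.64), Sgo1 (-1.58) and Smc3 (-1.25) were lower. The other way, 15 of 18 Sertoli markers (median -1.69, percentile 0), all 7 Leydig markers (-1.32, percentile 3.30), 13 of 17 stromal markers (-0.76, percentile 2.26) and 35 of 38 X-linked genes (-1.66, percentile 0) were lower in the fraction. Recombination genes were lower too (14 of 21, median -0.77, percentile 0.99), with Tex15 falling by 3.24 and Mnd1 by at least 4.92-fold, as were spermatogonial markers (12 of 16, median -1.21, percentile 0.23). Retrogenes were higher (11 of 13, median 0.82, percentile 99.68). Macrophage and blood markers had a median of 0.14 (percentile 88.09, 4 higher and 3 lower), and of -0.17 with the values as deposited. The split of calls was 692 higher and 351 lower with median scaling, 684 and 827 with the values as deposited, and 476 and 444 with the shared probe sets. The median over genes above the floor in both groups shifted by 0.33 with median scaling, 0.15 with the shared probe sets and 0.13 with quantile normalization.

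The extremes of this comparison lay largely outside the germ cell lists. Among the named genes that rose in the fraction were response genes. Fos rose by 5.02, with signals of 5015 in pachytene, 154.1 in whole testis and 11645 in spermatogonia. Socs3 rose by at least 9.53-fold, and the chemokine genes Cxcl1 and Cxcl2 by at least 8.95-fold and 8.86-fold. Of 23 measured immediate-early and stress genes 15 were higher in pachytene than in whole testis and 4 lower (median 1.22, percentile 100). Tex22 (4.68), Cep164 (3.83), Tmem120a (3.80), Brd2 (3.74), Abcc3 (3.48) and Csl (at least 7.05-fold) completed that end. At the other end, whole testis carried transcripts of digestive organs that were far lower in the fraction. Apoa4 was at least 111-fold, Apoa1 at least 107-fold, Fabp1 at least 81.4-fold and Fabp2, the intestinal fatty acid binding protein, at least 78.6-fold lower in pachytene; Fabp2 had a signal of 6887 in whole testis and 10706 in the somatic mix. Pancreatic enzyme genes Ctrb1 (-5.23), Cela1 (-4.74), Cel (-4.52) and Prss2 (-4.12) fell as well, as did Lpl, the lipoprotein lipase gene (-4.91), and Spink8, a protease inhibitor of the epididymis (-6.09). Across the arrays, 106 genes were at least 4-fold above all 3 fractions in both whole testis and the somatic mix. They are by definition among the 606 genes lower in pachytene. Whole testis also had the highest ratio of 3' to 5' control probe signal for Gapdh, 4.33 and 3.75 on the 2 designs against 1.49 and 1.52 in pachytene.

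**Figure D4:**
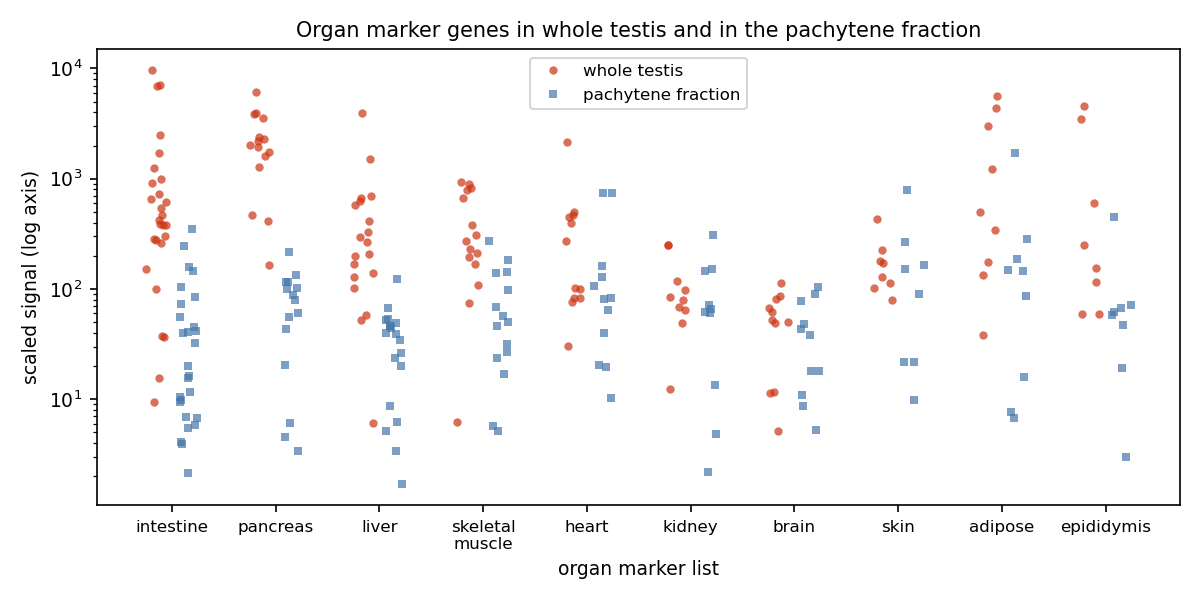
Scaled signal (y axis, log scale) of marker genes of 10 organs (x axis) in whole testis (red circles) and in the pachytene fraction (blue squares), each point being 1 gene. Median whole testis signal was 422 for the intestine list and 2029 for the pancreas list; brain and kidney markers were at 52.1 and 82.0.

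Whole testis against the somatic mix separated germ cell genes from organ genes. There were 1081 genes at least 4-fold higher and 853 at least 4-fold lower in testis, of 14976 measured (1288 and 665 with the values as deposited). The median over genes above the floor in both groups shifted by 0.22 in that setting and by 0.18 with median scaling. Several germ cell lists stood apart. The synaptonemal complex list had a median of 3.88 (11 of 15 rose), the piRNA list 3.74 (14 of 18) and the pachytene markers 3.53 (22 of 25). The recombination genes were at 1.83 (9 of 20), like these at percentile 100, and the segregation list at 1.16 (8 of 34, percentile 99.99). Spermatogonial markers did not stand apart (0.43, percentile 91.25). Ldhc rose by 7.54, Gtsf1, a piRNA pathway gene, by 6.31, Shcbp1l by 6.13, Morn5 by 5.98, Syce1 by 5.76 and Spa17 by 5.74. Against the floor, Cst12 was at least 126-fold, Rsph1 at least 115-fold, Fabp9 at least 106-fold and Spata4 at least 99.3-fold higher. Sertoli markers were also higher in testis (median 2.06, percentile 100), with Cst9 at least 72.7-fold and Aard at least 60.7-fold higher, both below the floor in the mix. The somatic organ list had a median of -2.37 (percentile 0), and 20 of 29 members fell. Macrophage and blood markers were lower as well (10 of 12, percentile 0). Immediate-early genes had a median of -0.47 (percentile 0.08), within the error limit of 0.57, with 10 of 22 lower and 5 higher. The arrays compared here also differed in the ratio of 3' to 5' control signal, which for Gapdh was 4.33 and 3.75 in whole testis against 1.21 and 1.18 in the mix, and for beta-actin 5.22 and 6.57 against 1.88 and 2.30. The named genes that fell were mostly heart and muscle genes. They included Nppa, the atrial natriuretic peptide gene (-6.41), Mb, encoding myoglobin (-5.72), Ckm (-5.38), Pln (-5.38) and Cox8b (-5.34). Against the floor, Myl3 (at least 107-fold), Tnnc1 (at least 84.5-fold) and Myl7 (at least 74.9-fold) fell. The kidney gene Kap (-5.64) and the liver gene Gnmt (at least 60.7-fold) were named too. The naming rule left out other large falls, such as that of the kidney gene Miox, at most 1.68% of the mix. Apoa1 (-1.07) and Fabp2 (-0.64) differed much less, as described above. The X-linked list (0.02) and the replication list (0.25) lay within the random lists, the former at -0.06 with the shared probe sets.

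Each fraction was also compared with the somatic mix. Spermatogonia had 572 genes higher and 950 lower, leptotene/zygotene 791 and 1067, and pachytene 1743 and 1823. With the values as deposited the splits were 859 and 839, 1257 and 893, and 2131 and 1584; with median scaling they were 752 and 810, 963 and 912, and 2514 and 1172; with the shared probe sets leptotene/zygotene had 552 and 1215. The median over genes above the floor in both groups shifted too, given in that order of fractions. As deposited it moved by 0.22, 0.34 and 0.31, and with median scaling by 0.20, 0.19 and 0.42. With the shared probe sets it moved by -0.21, -0.21 and 0.13, and in pachytene by 0.14 with quantile normalization. The synaptonemal complex list was above the mix in all fractions, with medians of 2.47, 3.44 and 3.71 in that order, and the piRNA list with 2.34, 2.85 and 3.50, all at percentile 100. The pachytene marker list moved from 0.90 (percentile 93.76) and 1.61 (percentile 99.99) to 4.94 (percentile 100). Sertoli markers were at 2.31 in spermatogonia and 2.27 in leptotene/zygotene, both at percentile 100, and at 0.40 in pachytene (percentile 79.89). Leydig markers were at 2.59 and 1.95 in the first 2 fractions. X-linked genes were at 0.72 and 0.73 and then at -1.64 (percentile 0). Immediate-early and stress genes were at 2.77 and 2.09 (percentile 100) and at 0.64 in pachytene (percentile 84.71). Organ markers were at -4.45, -4.45 and -5.02.

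A screen for meiotic prophase genes asked which genes were at least 4-fold above both spermatogonia and the somatic mix. It took 1179 genes, 1174 of them in pachytene, 33 in leptotene/zygotene and 28 in both stages; 625 came from the first array design and 554 from the second, and 171 were unnamed clones. The brightest, by the mean log2 signal of leptotene/zygotene and pachytene, were Ldhc, Rsph1, Gstm5, Hsbp1, Gkap1, Rpl39l, Lyar, Pgp, Phf7 and Nasp. Of these, Rsph1 had signals of 365, 2244 and 15701 in the 3 fractions and 43.2 in the mix, and Phf7, a histone reader of male germ cells, 408, 1721 and 15312. Gstm5, Hsbp1 and Pgp entered in pachytene only and were bright in both references. They read 2860, 3639 and 1175 in spermatogonia, and 2074, 2669 and 1007 in the mix. Gkap1, Rpl39l and Hsbp1 were only 4.01-fold, 4.05-fold and 4.29-fold above spermatogonia in pachytene. The screen held 24 of the 28 pachytene markers on the arrays, 5 of 15 synaptonemal complex and cohesin genes (Stag3, Syce1, Syce3, Sycp2 and Terb1), 4 of 22 recombination genes (Meiob, Psmc3ip, Spo11 and Brme1, carried on the arrays as 4930432K21Rik) and 8 of 20 piRNA genes. From the 39 segregation genes it took 7, namely Aurka, Aurkc, Ccna1, Ccnb2, Meikin, Plk1 and Ttk. It also held 7 of 16 retrogenes, 2 of 24 spermatid markers, 2 of 23 spermatogonial markers (Dmrtb1 and Id4) and 1 of 20 members of the Sertoli list (Rhox5). No member of the replication, Leydig, stromal, macrophage, organ, X-linked or immediate-early lists entered. The 5 genes found in leptotene/zygotene alone were Kif26a, Kif27, Meiob, Rhox5 and Tsx, of which the kinesin genes Kif26a and Kif27 are named after their values were seen.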

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

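The control probe sets described here were looked at beside the planned comparisons, and no explanation of their values was tested. They drew attention because the 18S signal, or the ratio of 3' to 5' signal, lay above that of the somatic mix on some arrays. The 3' probe set of the 18S ribosomal RNA control read 2174 in spermatogonia on the first array design and 2716 on the second, and 1801 and 1814 in leptotene/zygotene, against 526.1 and 573.3 in the somatic mix. In pachytene it read 427 and 342, and in whole testis 176 and 154. Nearer the 5' end the gap to the mix was smaller. On the first design the middle and 5' probe sets read 602.8 and 349.9 in spermatogonia and 354.5 and 195.2 in leptotene/zygotene, against 299.2 and 181.5 in the mix. On the second they read 692.0 and 378.4, and 355.1 and 202.8, against 318.4 and 175.1. The ratio of 3' to 5' signal of the Gapdh control was 4.33 and 3.755 in whole testis on the 2 designs, against 1.208 and 1.183 in the somatic mix. The same ratio for beta-actin was 5.219 and 6.569 in whole testis, against 1.875 and 2.301 in the mix. The fractions lay between, at 3.33 and 3.40 in spermatogonia, 3.18 and 3.13 in leptotene/zygotene, and 2.41 and 2.88 in pachytene.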

How the results depend on the processing

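The receptor floor on both designs, the comparisons without genes of other organs and the fits with a replicate block were chosen after seeing the data, and the other alternatives before. Of 270 counts recomputed under the alternatives, 173 stayed within 1.5 times the reported count and 97 did not. Of 878 values of named genes 569 moved by less than the error (1 SD) of their comparison and 309 by more, and of 1631 list medians 1156 and 475. No named gene changed direction under an alternative. These genes had been chosen for differences of at least 4-fold, so a change of sign was unlikely from the start. Of 128 list medians, 21 changed sign under at least 1 alternative, 10 of them under a scaling. None of the 85 with a percentile under 1 or over 99 did, but these too had been picked as extreme. No count moved past 1.5 times with the receptor floor on both designs, with a floor at the 40th percentile or with plain probe sets. Without genes of other organs, 500 genes were lower in pachytene than in whole testis and 795 lower in whole testis than in the mix, a change fixed by which genes were left out. Each reported gene rests on 1 array per group, so leaving out 1 sample leaves it no value. The 100 probe sets on both designs had 2 samples per group, and limma was fitted to them with and without the replicate number, which is also the array design, as a block. Without the block and then with it, higher and lower probe sets at an adjusted p under 0.05 were 5 and 5, then 7 and 7 in leptotene/zygotene against spermatogonia, and 20 and 50 both times in pachytene against leptotene/zygotene. All 16 counts over the 8 comparisons stayed within 1.5 times. Whether the numbers mark separate preparations is not given, and leaving out 1 sample was not run for these probe sets. Signal over background limits the decreases: a gene near the floor cannot show a 4-fold drop, and 73 of 100 simulated 8-fold decreases were called.

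With quantile normalization, pachytene against leptotene/zygotene had 811 lower, pachytene against whole testis had 389 lower. With median scaling, pachytene against leptotene/zygotene had 741 lower, pachytene against spermatogonia had 1087 lower, pachytene against whole testis had 692 higher and 351 lower, pachytene against somatic mix had 1172 lower. With the values as deposited, pachytene against whole testis had 684 higher, spermatogonia against somatic mix had 859 higher, leptotene/zygotene against somatic mix had 1257 higher. With scaling to the shared probe sets, pachytene against leptotene/zygotene had 604 lower, pachytene against spermatogonia had 993 lower. With a floor at the 60th percentile, leptotene/zygotene against spermatogonia had 17 higher, pachytene against leptotene/zygotene had 777 lower, pachytene against whole testis had 316 lower, whole testis against somatic mix had 565 lower, spermatogonia against somatic mix had 605 lower, leptotene/zygotene against somatic mix had 494 higher and 688 lower, pachytene against somatic mix had 1173 lower, the screen held 15 in leptotene/zygotene. With the log2 of signal plus floor, leptotene/zygotene against spermatogonia had 17 higher and 15 lower, pachytene against leptotene/zygotene had 633 lower, pachytene against spermatogonia had 962 lower, pachytene against whole testis had 185 higher and 263 lower, spermatogonia against somatic mix had 357 higher, leptotene/zygotene against somatic mix had 469 higher, the screen held 16 in leptotene/zygotene. With the mean over probe sets, pachytene against whole testis had 391 lower. On the first array design alone, leptotene/zygotene against spermatogonia had 24 higher and 23 lower, pachytene against leptotene/zygotene had 620 higher, pachytene against spermatogonia had 755 higher, pachytene against whole testis had 164 higher, whole testis against somatic mix had 632 higher, pachytene against somatic mix had 1049 higher, the screen held 18 genes in leptotene/zygotene, 623 in pachytene and 625 in either stage. On the second array design alone, leptotene/zygotene against spermatogonia had 20 higher, pachytene against leptotene/zygotene had 634 higher and 504 lower, pachytene against spermatogonia had 704 higher and 696 lower, pachytene against whole testis had 187 higher and 192 lower, whole testis against somatic mix had 508 higher and 261 lower, spermatogonia against somatic mix had 273 higher and 253 lower, leptotene/zygotene against somatic mix had 326 higher and 315 lower, pachytene against somatic mix had 807 higher and 651 lower, the screen held 18 genes in leptotene/zygotene, 626 in pachytene and 630 in either stage. With a 2-fold threshold, leptotene/zygotene against spermatogonia had 441 higher and 617 lower, pachytene against leptotene/zygotene had 2430 higher and 3746 lower, pachytene against spermatogonia had 2725 higher and 4056 lower, pachytene against whole testis had 1761 higher and 2834 lower, whole testis against somatic mix had 2874 higher and 2758 lower, spermatogonia against somatic mix had 2531 higher and 2540 lower, leptotene/zygotene against somatic mix had 2965 higher and 2823 lower, pachytene against somatic mix had 3362 higher and 4682 lower, the screen held 332 genes in leptotene/zygotene, 2352 in pachytene and 2480 in either stage. With an 8-fold threshold, leptotene/zygotene against spermatogonia had 5 higher and 2 lower, pachytene against leptotene/zygotene had 584 higher and 135 lower, pachytene against spermatogonia had 728 higher and 298 lower, pachytene against whole testis had 25 higher and 95 lower, whole testis against somatic mix had 443 higher and 266 lower, spermatogonia against somatic mix had 172 higher and 463 lower, leptotene/zygotene against somatic mix had 216 higher and 506 lower, pachytene against somatic mix had 914 higher and 689 lower, the screen held 5 genes in leptotene/zygotene, 638 in pachytene and 639 in either stage. The thresholds of 2-fold and 8-fold and the single designs change the counts by their construction, since they call at another size or hold fewer genes. For the other settings the cause was not tested.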

Other observations

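The tests below were chosen after the result was seen, except the test on X-linked genes at the floor in the mix and the test on the second array design, which were written down first. The organ marker lists were also written after the named genes had been seen. The intervals are over genes read from single arrays, so they hold no difference between preparations or animals.

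Whole testis carried transcripts of several organs that were lower in the 3 fractions. Adipoq, an adipocyte hormone, had a signal of 2982 in whole testis and 794.6 in the somatic mix, and Fabp4, an adipocyte fatty acid binding protein, 4366 and 3449. The epididymal genes Defb42 and Spink8 read 3454 and 4597 in whole testis, and 435.7 and 172.3 in spermatogonia. These are picked members: in whole testis 3 of 8 epididymal and 4 of 9 adipose genes measured were at least 4-fold above all fractions. Others went the other way, such as Rnase10 (155.7 against 446.2 in pachytene) and Cidea (341.7 against 1112.5 in spermatogonia). Median differences between whole testis and mix, in log2, were -1.87 for the intestine list, -2.94 for pancreas, -3.50 for skeletal muscle, -4.04 for liver, -4.42 for heart, -3.18 for kidney, -1.74 for brain, -1.03 for skin, -2.27 for blood, 1.41 for epididymis and -0.19 for adipose tissue. The floor compresses several of these, since 4 of 10 kidney and 3 of 11 brain members were above it in whole testis. Lists other than epididymis and adipose kept only members above the floor in the mix. The epididymal Adam7, Gpx5 and Spink10 were at the floor in the mix and entered because whole testis was above it. The epididymis median is therefore raised by the rule, and the 8 epididymal genes counted above include these. Of the others, Lcn8, Lcn9 and Rnase10 lay at 96.2%, 122.9% and 90.8% of the mix, Defb42 and Spink8 at 2696% and 2966%. Over members bright in the mix and at the floor in all fractions, kidney lay at -4.85, blood at -4.51 and heart at -6.23 (4, 2 and 3 genes). Pancreatic enzyme genes were bright in the mix, Cela2a at 20181 and Prss2 at 19499, although pancreas is not among its named tissues. Across the 436 X-linked genes measured in pachytene against leptotene/zygotene, 1 rose, Tsga8 (at least 10.9-fold), named after its value was seen.

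Gut transcripts in whole testis may come from other tissue or RNA in that sample, and an even share of the somatic mix is argued against as their whole cause. Such a share would put all organ lists at 1 ratio, but without the genes named for their values, 24 intestine genes lay 2.12 above the 19 liver genes, the largest other list (95% interval 0.76 to 2.43), and 4 of 9 lists lay below intestine with their intervals and adipose above it. The other 4 (kidney, brain, skin and blood) had intervals across 0. Over bright members, intestine lay 2.87 above 4 kidney genes (1.43 to 3.92) and 2.53 above 2 blood genes. Intervals resampled from so few genes are not reliable, so kidney and blood stay undecided. It lay 2.29 above 11 liver genes (1.28 to 2.43) and 1.66 above 7 muscle genes (0.755 to 2.5). Bright pancreas (1.02, -0.65 to 2.02) and adipose genes (-2.32, -4.54 to 1.19) had intervals across 0, the latter from 3 genes only. Brain, skin and heart had too few bright members. This test was computed in several versions, with the lists, the members and the rule changed after earlier gaps had been seen: all 97 members of the other lists had left the question open (0.74, 0.04 to 1.39), and their 37 bright members gave 1.94 (0.87 to 2.26). A smaller even share stays open for the liver transcripts, at -0.69 from skeletal muscle (-1.76 to 0.54), and gut tissue stays open under a rule also set afterwards, since intestine stood -1.91 from the highest list, adipose (-3.10 to -1.16), and 2.26 above the lowest, heart (0.55 to 2.95), as does a reading error of the first design, since 5 probe sets on the second gave 0.59 (-0.20 to 3.04), and expression by testis cells outside the fractions was not tested.

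Immediate-early and stress genes were above whole testis in all 3 fractions, and a response to tissue dissociation may contribute. In pachytene a larger share of Sertoli, Leydig or stromal cells is argued against, since the list lay at least 1.98 above each of theirs (1.06 to 2.77), but macrophages or blood cells stay open, their median being 0.14 above whole testis and 1.08 below the list (-0.01 to 1.91). In spermatogonia and leptotene/zygotene Sertoli and Leydig medians were themselves above whole testis, by 1.06 and 1.28 and by 0.83 and 0.60, as was the stromal median in spermatogonia (0.74), so a somatic share is argued against only as the whole cause: the list rose beyond each of the 4 somatic lists, and the gap with the lowest bound was 2.28, to Leydig markers in spermatogonia (0.68 to 2.98). RNA weighted to the 3' end in whole testis is argued against for these fractions only as the whole cause. They lay at least 2.08 above the somatic mix (1.47 to 3.26), a pool of other cell types. The beta-actin ratio of the mix (1.88 and 2.30) was below that of spermatogonia (3.33 and 3.40) and leptotene/zygotene (3.18 and 3.13). The mix is thus not a reference with ratios like theirs. The medians of these fractions above whole testis were larger (3.555 and 3.021), so a part of 3' weighting stays open. For pachytene neither 3' weighting nor dissociation can be decided, because its median above the mix was 0.64 (-0.10 to 1.33). Age and cell type differ between the samples too, and their part was not tested.

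The lower X-linked signal in pachytene may reflect lower X chromosome RNA in pachytene cells, a hypothesis found and tested on the same arrays. The X median minus the lowest autosome median was -1.34 log2 (-1.57 to -1.10). A smaller somatic share is argued against as the whole cause, since among genes at the floor in the mix and higher in leptotene/zygotene than in spermatogonia, 64 X-linked genes lay -1.89 from 813 autosomal ones (-2.35 to -1.28). That set held 3 somatic list members, Rhox5 among them. Without these and with genes higher beyond the error limit, a set chosen afterwards, 43 X-linked genes lay -2.35 from 491 autosomal ones (-2.81 to -1.61). The mix holds no testis, so genes of testis somatic cells outside the short lists can remain in both sets. These gaps therefore argue against a somatic share only as far as such genes do not carry them. The test on scaling decides nothing. Each of the 5 scalings moves genes of like signal on an array alike, so the X minus autosome gap could hardly close under any. It was -1.26 (-1.41 to -1.10) with quantile normalization, the only one that does not move all genes of an array alike. With the values as deposited it was -1.50 (-1.65 to -1.34).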
